A study of Homo sapiens with 6 samples.

How the data were processed

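RNA sequencing was done on total RNA of OCI-AML2, an established human acute myeloid leukaemia line. Per the labels' protocols, short hairpin RNAs were delivered by lentivirus, cells were selected in puromycin at 2.0 µg/mL for 3 days, RNA was purified with a column kit and libraries were made with a directional kit. There are 6 libraries in 3 groups of 2, lettered A and B: a control hairpin, TAZ shRNA1 and TAZ shRNA2. The labels call the control hairpin a scramble sequence, while the control columns of the deposited tables carry the name GFP; they were taken as the control libraries because the table titles name the control group and no other group is left. Columns were matched to libraries by table title and letter, and 0 columns stayed unmatched.

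Per the submitters' processing notes, the tools Trim Galore 0.4.0, TopHat2 2.0.11, HTSeq 0.6.1p2, edgeR 3.8.6 and DESeq 1.18.0 and the genome build hg19 were used, with no role or order stated. Per the file headers, the authors deposited 1 table per hairpin, with 13004 genes and the RPKM (reads scaled by gene length and by library depth) of each of the 4 libraries of that comparison. Each deposited table also holds the authors' log2 fold change and average log2 CPM, a likelihood-ratio score and its p-value with an adjusted p-value. The 2 control columns held the same values in both tables, so all 6 libraries share 1 normalization. The rule by which the authors filtered genes and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be separated. Paralogs with near-identical sequence (histone, HLA, IFITM and ribosomal protein genes, and the pseudogene RP9P) are uncertain for a similar reason.

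In the tables, 21 symbols had been turned into dates and were named again through their gene ID, and 2 exact repeats (SFPQ and CSNK1E) were dropped, which left 13002 genes. Within a library, RPKM values of a gene are whole multiples of what 1 read is worth. From these steps whole reads were recovered for 12407 genes (95.4%, within 0.05 reads of a whole number). The other 595 genes were scaled by the authors' average log2 CPM. Recovered reads gave the depth: 18848045 reads in listed genes in control A, 20049893 in control B, 20782362 and 20995024 in shRNA1 A and B, and 19925101 and 18845475 in shRNA2 A and B. The 10 most abundant genes took 8.02% to 9.14% of these reads. Gene lengths used below are those implied by the recovered reads. The RPKM denominators were not proportional to the reads in listed genes (shRNA2 B over control A was 1.12 by denominators and 1.00 by listed reads), so they include reads outside the listed genes or another scaling. The date-like symbols were named through a RefSeq gene list. GENCODE release 29 was used for GC content and a check of gene lengths only, and 97.6% of genes had a transcript in it by gene ID. It is on another build than hg19, so no coordinates are given.

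Each hairpin was compared with the control in its own table of 4 libraries. Values were transformed to log2(RPKM + 0.5), genes with a mean of at least 1 RPKM over the 4 libraries were kept, and limma 3.58.1 (R 4.3.3) was fitted with a prior variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every gene-level adjusted p printed without another name is limma's, and every level is a mean ± SD of the 2 libraries of a group. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes near 0. The difference between the hairpins was tested in one fit of all 6 libraries. Lists of genes were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 tested genes, adjusted over the lists. Of 39 lists, 37 could be tested for shRNA1 and 36 for shRNA2. The same lists were run with an estimated correlation and with fry. Fry asks whether a list moves on balance without comparing it with other genes. With 2 libraries per group, the run with an estimated correlation rests on very few degrees of freedom. It could hardly reach the threshold, so a list that did not pass in it stays undecided. Its smallest unadjusted camera p over lists was 0.143 with shRNA1 and 0.0487 with shRNA2. It was not part of the check on simulated data. The agreement of the hairpins was set beside 100 simulated draws of unchanged groups against the same control libraries. Bootstrap intervals of lists resampled their genes 2000 times, so they measure the spread over genes and not over libraries.

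The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Named genes are TAZ; the 10 genes that rose and the 10 that fell most with both hairpins (ranked by the smaller change); the 5 that rose and the 5 that fell most with each hairpin; and up to 4 members per list with the smallest value of the larger p of both comparisons, called or not. Genes of the first kinds had to have libraries that did not overlap the control, and sex-linked marker genes and unnamed transcripts were left out of them. WWTR1, which shares the protein name TAZ, and the genes of mitochondrial DNA were to be named too and were not analysed here.

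Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at a mean of 5 RPKM, quantile normalization, median centring on genes of at least 10 RPKM, no variance trend, robust empirical Bayes, the letters as a block, all libraries in one fit, each library left out in turn, a minimum of 2-fold change and the authors' statistics. Added after the data were seen were limma-voom on the recovered reads and the removal of each library's trend with gene length or GC content. A split of the control libraries with 1 per hairpin was added then too. The voom run fitted all 6 libraries at once. The tests were checked on simulated data. In the simulation of the shRNA1 comparison with 10613 genes, 97% of genes made to change by a log2 fold of 1 were called with the right sign, and 9.22% of calls fell on unchanged genes. For the shRNA2 comparison with 10659 genes these values were 89% and 7.84%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.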

Results

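Gene expression was measured in OCI-AML2 leukaemia cells carrying a control hairpin or either of 2 independent hairpins against TAZ, with 2 libraries per group. TAZ encodes tafazzin, the mitochondrial enzyme that remodels the acyl chains of cardiolipin. The series title names cell state and the levels of phosphatidylethanolamine and phosphatidylserine as its subject. Each library had between 18845475 and 20995024 reads in listed genes. Across genes, which are not independent replicates, log2 values of libraries A and B correlated at r = 0.986 in the control, 0.994 with shRNA1 and 0.990 with shRNA2. The SD of the log2 difference between A and B was 0.34 in the control, 0.21 with shRNA1 and 0.29 with shRNA2, above counting noise in each group. The labels do not say that A and B came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

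TAZ itself (gene ID 6901) was lower in all 4 knockdown libraries than in both control libraries. It stood at 11.3 and 11.9 RPKM in the control libraries, at 4.02 and 4.10 RPKM with shRNA1 and at 1.47 and 2.13 RPKM with shRNA2. These levels rest on 387 and 463 reads in the control, 159 and 166 with shRNA1, and 55 and 82 with shRNA2. The log2 fold change was -1.41 (SE 0.13) with shRNA1 and -2.41 (SE 0.18) with shRNA2, with limma adjusted p of 0.00205 and 0.00245. TAZ was lower with shRNA2 than with shRNA1 by a log2 fold change of -1.001 (adjusted p = 0.00801). That difference lay between -0.79 and -1.21 with each library left out, and its call was lost without either shRNA1 library. The authors' deposited table gives log2 fold changes of -1.52 and -2.68.

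**Figure D1:**
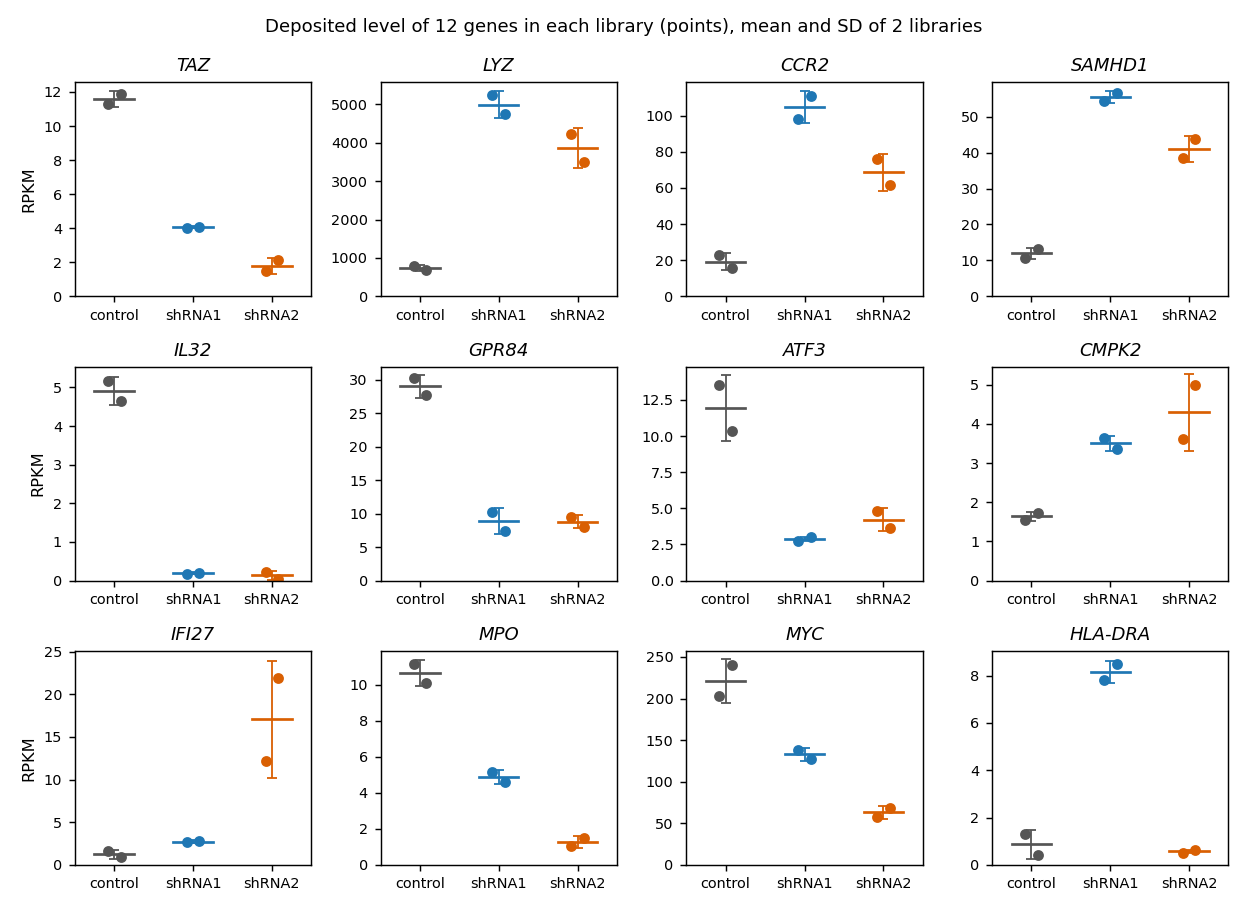
Deposited RPKM of 12 genes (vertical axes, each from 0) in the control, shRNA1 and shRNA2 libraries; points are libraries, lines are means and bars are the SD of 2 libraries. TAZ lies at 11.3 and 11.9 RPKM in the control and at or below 4.10 RPKM in all 4 knockdown libraries.

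With shRNA1, the question was which transcripts differed from the control hairpin when TAZ was lowered. LYZ, the lysozyme of monocyte and granulocyte granules, rose 6.83-fold from 731 ± 77.6 to 4989 ± 349 RPKM (SD, n = 2). The defensin gene DEFB1 rose from 62.0 ± 21.9 to 399 ± 38.3 RPKM, PTGDS, which makes prostaglandin D2, from 0.134 ± 0.103 to 5.52 ± 0.285 RPKM, and HLA-DRA, a chain of MHC class II, from 0.864 ± 0.625 to 8.15 ± 0.474 RPKM. The cytokine genes IL32 and LTB fell from 4.91 ± 0.369 to 0.186 ± 0.0263 RPKM and from 17.7 ± 2.85 to 2.07 ± 1.06 RPKM. H2AFX, the histone variant that marks DNA breaks, fell from 69.8 ± 6.96 to 11.8 ± 1.19 RPKM, and DEFA4, a neutrophil defensin, from 33.5 ± 11.2 to 4.16 ± 0.0681 RPKM. TMEM255A rose by a log2 fold change of 2.75 (SE 0.21). Adjusted p for these genes lay between 0.00101 and 0.00317. Of 10613 genes tested with limma, 1060 rose and 911 fell, and 225 and 154 of them by at least 2-fold. Without shRNA1 B 500 genes were called, without shRNA1 A 811, without control A 3286 and without control B 4447. The authors' deposited table calls 4662 genes, and 1950 of the 1971 genes called here are among them with the same sign.

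Among gene groups, targets of the integrated stress response, the ATF4 programme of amino acid and protein stress, were lower with shRNA1. Of 38 tested, 12 fell and 26 did not pass, and 16 fell adjusted over the list alone. ATF3 fell by 1.87 on the log2 scale (SE 0.17, adjusted p = 0.00187), TRIB3 by 1.47 (SE 0.17, adjusted p = 0.00366) and DDIT4 by 1.33 (SE 0.18, adjusted p = 0.00563). The list's median log2 fold change was -0.72 (camera adjusted p = 1.12e-06), -0.30 without control B (0.00177) and -1.08 without control A. CHAC1, a glutathione-degrading enzyme of this list, stood at 2.15 and 13.0 RPKM in control A and B and at 0.478 ± 0.247 RPKM with shRNA1. Its log2 fold change was -2.63 (adjusted p = 0.0326), -1.46 without control B and -3.81 without control A, and its adjusted p was 0.166 with robust empirical Bayes. Immediate early genes, which respond within minutes to growth signals, were lower, with 14 of 25 falling and 11 not passing (15 fell and 2 rose adjusted over the list alone). JUND fell from 152 ± 29.5 to 42.1 ± 4.97 RPKM and IER2 from 91.1 ± 17.7 to 30.5 ± 8.50 RPKM. The list's median was -0.74 (camera adjusted p = 4.51e-05). Of 22 NF-kappaB and inflammatory targets 8 fell and 1 rose, SERPINB2, while 13 did not pass (12 fell and 1 rose adjusted over the list alone). CD83, a surface protein of activated antigen-presenting cells, fell by 1.03 (SE 0.21, adjusted p = 0.0199). SERPINB2, a plasminogen activator inhibitor, rose by 0.90 (adjusted p = 0.0128), a call lost without either shRNA1 library. The list's median was -0.60 (camera adjusted p = 0.000417). With an estimated correlation these lists had an adjusted p = 0.852.

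Transcripts of both ribosomes were lower with shRNA1 by small amounts. Of 42 genes of the mitochondrial ribosome and its translation factors 11 fell and 31 did not pass (13 fell adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 2.32e-05), and -0.11 with the trend over gene length removed from each library (0.0393). MRPL2 fell from 70.4 ± 6.16 to 41.8 ± 1.13 RPKM (adjusted p = 0.0093), a call lost without shRNA1 B. Of 76 cytosolic ribosomal protein genes 73 had lower values, but limma called 1 fall over all genes. Adjusted over the list alone it called 0, 17 were lower at an unadjusted p under 0.05, limma-voom on recovered reads called 5, and the authors' deposited table calls 41. The median of this list was -0.35 (camera adjusted p = 6.04e-06), -0.17 without control A (0.000591) and -0.55 without control B. With the gene length trend removed it was -0.04 (camera adjusted p = 0.179). Genes of ribosome biogenesis and other MYC targets had a median of -0.23 (camera adjusted p = 0.0125), with 3 of 37 falling and 34 not passing, also adjusted over the list alone. That call was lost without control B (adjusted p = 0.0619), without shRNA1 B (0.115) and with quantile normalization (0.154). Nuclear-encoded genes of oxidative phosphorylation had a median of -0.19 (camera adjusted p = 0.0185), with 1 of 77 falling, 2 rising and 74 not passing. Adjusted over the list alone limma called 0 of them, against 10 lower and 5 higher at an unadjusted p under 0.05, 1 fall and 2 rises by limma-voom, and 20 falls and 4 rises in the authors' deposited table. That median was -0.02 without control A (0.935), -0.33 without control B, -0.15 without shRNA1 B (0.115), -0.06 with quantile normalization (0.564) and 0.10 with the gene length trend removed (0.045). With an estimated correlation these 4 lists had an adjusted p = 0.852.

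Some groups of myeloid maturation and antigen presentation were higher with shRNA1. Of 37 genes of monocyte and macrophage differentiation 13 rose, 5 fell and 19 did not pass (16 rose and 5 fell adjusted over the list alone). CCR2, the receptor by which monocytes leave the marrow, rose from 19.3 ± 4.92 to 105 ± 8.88 RPKM, CD36, a scavenger receptor, from 0.918 ± 0.178 to 2.95 ± 0.220 RPKM, and LILRB4, an inhibitory myeloid receptor, from 3.57 ± 0.335 to 8.36 ± 0.211 RPKM. The list's median was 0.25 (camera adjusted p = 0.00894), 0.61 without control A and 0.11 without control B, where the call was lost (0.165). Of 34 interferon stimulated genes 10 rose and 24 did not pass (14 rose and 2 fell adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00797). Of 35 lysosome and autophagy genes 8 rose and 27 did not pass (10 rose adjusted over the list alone), LAMP2 from 25.6 ± 0.205 to 54.0 ± 3.30 RPKM and CTSA from 45.2 ± 3.20 to 85.1 ± 9.15 RPKM. The median of that list was 0.15 (camera adjusted p = 0.00797), 0.28 without control A and 0.08 without control B, where the call was lost (0.0619). Of 6 MHC class II genes 3 rose (5 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 0.00884). HLA-DRB1 rose from 0.499 ± 0.0745 to 2.60 ± 0.265 RPKM. HLA-DRA and HLA-DRB1, under 1 RPKM in the control, passed the filter only through their level with shRNA1. The count and median of this list therefore lean upward, and 3 of its genes could be tested with shRNA2. Fatty acid synthesis genes had a median of 0.32 (camera adjusted p = 0.0154), with 3 of 22 rising and 19 not passing. Adjusted over the list alone limma called 0 of them, against 11 higher at an unadjusted p under 0.05, 4 rises by limma-voom, and 11 rises and 1 fall in the authors' deposited table. The call of that list was lost without shRNA1 B (0.115) and with the gene length trend removed (0.0887). With an estimated correlation these 5 lists had an adjusted p = 0.852. Related lists were not called. Of 12 mature neutrophil genes 3 rose, 4 fell and 5 did not pass (3 rose and 6 fell adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.584). Of 13 genes of MHC class I presentation 1 rose, 3 fell and 9 did not pass (1 rose and 5 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.171).

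With shRNA2, the hairpin with the lower TAZ level, the same question was asked against the same control libraries. IFI27, an interferon stimulated gene, rose from 1.26 ± 0.523 to 17.1 ± 6.86 RPKM (SD, n = 2), and S100A12, a calcium-binding protein of monocytes and neutrophils, from 13.7 ± 6.61 to 104 ± 3.19 RPKM. SPP1, which encodes osteopontin, rose from 1.82 ± 1.61 to 15.4 ± 6.71 RPKM, and PTAFR, the receptor for platelet-activating factor, from 1.01 ± 0.673 to 9.52 ± 3.16 RPKM. PINLYP rose from 0.478 ± 0.447 to 5.66 ± 1.38 RPKM. IL32 fell from 4.91 ± 0.369 to 0.133 ± 0.127 RPKM, MZB1, an endoplasmic reticulum protein of antibody-making cells, from 6.02 ± 1.52 to 0.401 ± 0.312 RPKM, and VEGFA, the vascular growth factor, from 17.3 ± 6.89 to 2.17 ± 0.00795 RPKM. MPO, the myeloperoxidase of neutrophil primary granules, fell from 10.6 ± 0.732 to 1.25 ± 0.327 RPKM. Adjusted p for these genes lay between 0.00245 and 0.0103, and SPP1 lost its call with robust empirical Bayes (0.0599). CHAC1 had a log2 fold change of -2.64 (adjusted p = 0.0334), -1.46 without control B and -3.81 without control A, and its adjusted p was 0.14 with robust empirical Bayes. Of 10659 genes tested with limma, 865 rose and 811 fell, and 253 and 241 of them by at least 2-fold. Without shRNA2 B 864 genes were called. The authors' deposited table calls 5044 genes, and 1666 of the 1676 genes called here are among them with the same sign.

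Interferon stimulated and myeloid genes were higher with shRNA2. Of 40 interferon stimulated genes 21 rose and 19 did not pass (24 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 0.89 (camera adjusted p = 5.91e-11), and 0.81 over the 34 also tested with shRNA1. CMPK2, a nucleotide kinase induced by interferon, rose from 1.64 ± 0.114 to 4.29 ± 0.980 RPKM. Of 38 genes of monocyte and macrophage differentiation 19 rose and 19 did not pass (21 rose adjusted over the list alone), with a median of 0.70 (camera adjusted p = 6.06e-10). CD36 rose by 2.30 on the log2 scale (SE 0.18, adjusted p = 0.00245) and LILRB4 by 1.39 (SE 0.15, adjusted p = 0.00326). Of 35 lysosome and autophagy genes 11 rose and 24 did not pass (14 rose adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.59e-07). Of 45 genes of the Toll-like receptor pathway 12 rose, 3 fell and 30 did not pass (19 rose and 5 fell adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.000734). TLR8, a sensor of single-stranded RNA, rose from 0.40 ± 0.185 to 3.71 ± 0.545 RPKM, and TLR2, a sensor of bacterial lipoproteins, from 15.7 ± 2.04 to 32.6 ± 1.79 RPKM. TNF, a cytokine of this list, fell from 34.7 ± 3.05 to 19.4 ± 0.730 RPKM. Of 14 mature neutrophil genes 5 rose, 2 fell and 7 did not pass (9 rose and 2 fell adjusted over the list alone). CXCR2, a chemokine receptor, rose by 1.48 (SE 0.15, adjusted p = 0.00255) and MMP8, the neutrophil collagenase, by 1.95 (SE 0.21, adjusted p = 0.00317). MMP8 and FPR1 passed the filter with the shRNA2 libraries but not with the shRNA1 libraries, so the count and median of this list lean upward. The median of this list was 0.62 (camera adjusted p = 0.0102), and the call was lost without control B (0.276), with no filter (0.0611) and with a filter at 5 RPKM (0.147). Of 12 replication-dependent histone genes 6 rose, 1 fell and 5 did not pass (7 rose and 1 fell adjusted over the list alone), with a median of 0.82 (camera adjusted p = 0.00781), a call lost with no filter (0.0611). HIST1H2BK rose from 19.6 ± 1.73 to 84.9 ± 13.3 RPKM. With an estimated correlation these 6 lists had an adjusted p = 0.909.

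Growth and stress groups were lower with shRNA2. Of 37 MYC targets and ribosome biogenesis genes 14 fell and 23 did not pass (24 fell adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 2.82e-10). MYC itself, a transcription factor of cell growth, fell from 221 ± 26.3 to 63.0 ± 7.99 RPKM, and PES1, a ribosome assembly factor, from 85.4 ± 0.861 to 45.8 ± 2.05 RPKM. Of 38 integrated stress response targets 16 fell and 22 did not pass (26 fell adjusted over the list alone). ATF4, the transcription factor at its centre, fell from 527 ± 107 to 176 ± 14.3 RPKM and DDIT4 from 45.0 ± 11.9 to 12.8 ± 2.26 RPKM. The median was -1.02 (camera adjusted p = 6.06e-10), -0.52 without control B (7.78e-08) and -1.43 without control A. Of 42 mitochondrial ribosome and translation genes 8 fell and 34 did not pass (12 fell adjusted over the list alone), with MRPL10 falling by 1.62 (SE 0.15, adjusted p = 0.00245). That median was -0.37 (camera adjusted p = 6.59e-06), -0.22 without shRNA2 B (0.00504), -0.55 without shRNA2 A and -0.23 with the gene length trend removed (0.00047). All 76 cytosolic ribosomal protein genes had lower values, with a median of -0.37 (camera adjusted p = 0.000333), but limma called 0 of them, also adjusted over the list alone. At an unadjusted p under 0.05 3 were lower, limma-voom on recovered reads called 6, and the authors' deposited table calls 43. The median was -0.18 without control A (0.37), -0.19 without shRNA2 B (0.192) and -0.56 without control B, and -0.14 with the gene length trend removed (0.000631). Of 31 glycolysis and hypoxia genes 7 fell and 24 did not pass, also adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0053), 0.00 without control A (0.638) and -0.70 without control B. Of 18 heat shock and mitochondrial chaperone genes 4 fell and 14 did not pass, also adjusted over the list alone. LONP1, a mitochondrial protease, fell from 60.8 ± 8.37 to 35.3 ± 0.356 RPKM. The median of that list was -0.32 (camera adjusted p = 0.0111), -0.19 without control A (0.291) and -0.28 without shRNA2 B (0.12). With an estimated correlation these 6 lists had an adjusted p = 0.909. Fry called 0 lists with either hairpin, against 6 with an unadjusted p under 0.05 for each, and its smallest adjusted p was 0.204 with shRNA1 and 0.167 with shRNA2.

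**Figure D2:**
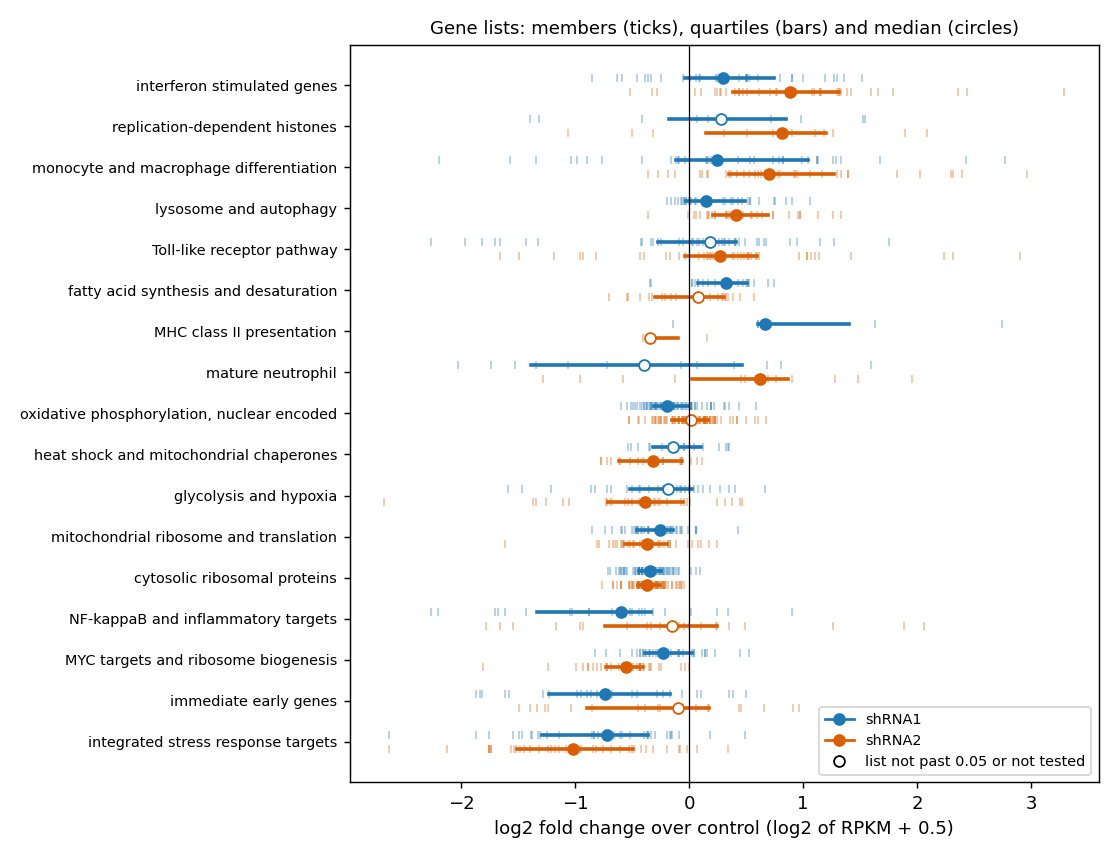
Log2 fold change over control (horizontal axis, log2 of RPKM + 0.5) for the lists called with at least 1 hairpin; ticks are genes, bars span the quartiles and circles are medians, open where the list did not pass 0.05 or was not tested. Medians run from -1.02 for integrated stress response targets to 0.89 for interferon stimulated genes, both with shRNA2.

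Genes that changed with both hairpins bear on the question of which responses 2 independent hairpins share. LYZ rose by 2.77 and 2.40 on the log2 scale with shRNA1 and shRNA2, CCR2 by 2.43 and 1.82, and SAMHD1, a myeloid dNTP hydrolase that restricts retroviruses, by 2.18 and 1.74. FGL2, a secreted fibrinogen-like protein, rose by 2.29 and 1.87, TLR8 by 1.75 and 2.24, and ECM1, an extracellular matrix protein, by 1.84 and 1.94. SIRPD and ARHGAP19 rose by 2.12 and 2.08, and by 1.94 and 1.79. IL32 fell by 2.98 and 3.11, ACY3, an aminoacylase, by 2.22 and 2.32, and RGS16, a regulator of G-protein signalling, by 1.99 and 2.59. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 1.80 and 1.72, GPR84, a receptor for medium-chain fatty acids, by 1.67 and 1.67, MFAP4 by 1.73 and 1.94, and RP9P by 1.65 and 1.79. DEFB1 (2.72 and 2.10) and PTAFR (1.85 and 2.76) rose and MZB1 (-1.72 and -2.88), LTB (-2.88 and -1.72) and CHAC1 (-2.63 and -2.64) fell with both, CHAC1 with an SE of 0.65 and 0.64. Apart from CHAC1, the SE of these changes lay between 0.13 and 0.33, and limma adjusted p between 0.00101 and 0.0134. Members of several groups changed with both. Of genes tested with both, 7 of 38 stress response, 6 of 24 immediate early and 5 of 42 mitochondrial ribosome genes fell. Those that rose were 9 of 37 monocyte, 8 of 34 interferon stimulated and 4 of 35 lysosome genes. Among them were TRIB3 (-1.47 and -1.48), ETV4 (-0.86 and -1.26), LILRB4 (1.12 and 1.39) and LAMP2 (1.06 and 0.96). Over all 10501 genes tested with both, 452 rose and 347 fell. Other lists went both ways with both hairpins. These included the Toll-like receptor pathway (6 rose, 3 fell), NF-kappaB targets (1 rose, 2 fell) and replication-dependent histones (3 rose, 1 fell).

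Of 10501 genes tested with both hairpins, 452 rose and 347 fell with both, and 14 were called in opposite directions. Independent lists of these sizes would share 80.5 genes that rose and 70.3 that fell, and unchanged groups against the same control libraries shared at most 1 in each direction in 100 simulated draws. Those draws held between 0 and 8 calls per comparison, too few for a shared count, so they do not test whether the hairpins share genes. Across genes, the log2 fold changes of the hairpins correlated at r = 0.659 (Spearman 0.655), beside 0.497 and 0.475 on average for unchanged groups. The covariance was 0.146, beside 0.0148 simulated, a difference of 0.131. Both fold changes had the same sign in 74.9% of genes, beside 66.7% simulated. The draws gave every library the same spread per gene. In the data, A and B differed more in the control (SD 0.34) than with shRNA1 (0.21) or shRNA2 (0.29). Noisier shared controls raise the correlation and the same-sign share of unchanged groups. The simulated values are therefore likely too low, by an amount that was not measured, and the excess over them is no test of agreement. With control A for shRNA1 and control B for shRNA2 the correlation was 0.419, the covariance 0.109 and the same-sign share 64.8%, and with the controls exchanged these were 0.523, 0.126 and 69.2%. Each split left 1 control library per hairpin, and part of the excess with both controls may come from the shared controls. No library served both hairpins in a split. The covariances of 0.109 and 0.126 therefore argue against noise of shared control libraries as the whole cause of the agreement. A state common to both control libraries is not separated by the splits and stays open. Shared controls also make opposite calls rarer. Both splits held more opposite calls than the 14 found with both controls, although their fits with a lone control library make such counts unsure. The 14 opposite calls and the excess over independent lists may therefore overstate the agreement. Without shRNA1 B 278 genes were called the same way with both, without shRNA1 A 417, without shRNA2 B 430 and without control B 1383.

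**Figure D3:**
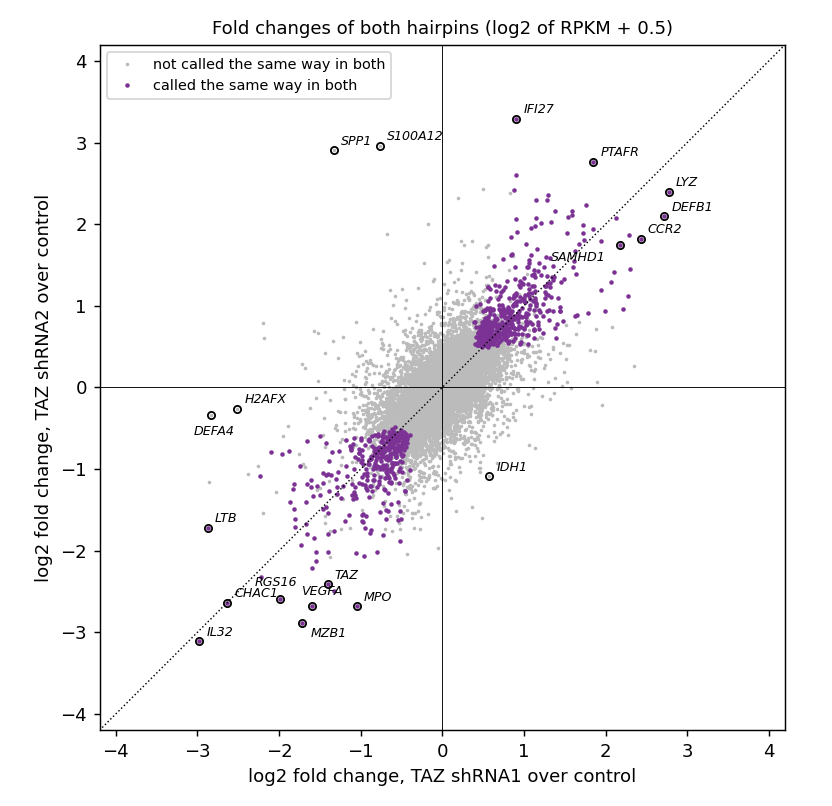
Log2 fold change with shRNA2 (vertical axis) against shRNA1 (horizontal axis), both over the same 2 control libraries, on log2 of RPKM + 0.5; each point is a gene, purple where called the same way with both, and the dotted line marks equal change. LYZ, CCR2 and SAMHD1 lie high with both hairpins, IL32 low with both, and H2AFX and DEFA4 far below 0 with shRNA1, while their values of -0.26 and -0.34 with shRNA2 did not pass.

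The hairpins differed in some of their strongest responses. SPP1 and S100A12 were higher with shRNA2 than with shRNA1 by log2 differences of 4.24 and 3.72, and IFI27 by 2.39. H2AFX and DEFA4 were higher with shRNA2 by 2.25 and 2.49, since they had fallen with shRNA1. HLA-DRA was lower with shRNA2 by -3.02, TMEM255A by -2.44 and PTGDS by -2.43, and MPO was lower by -1.63. MYC was lower by -1.07, a call lost without either shRNA1 library. IDH1, the cytosolic isocitrate dehydrogenase, stood at 47.8 ± 10.6 RPKM in the control, 70.7 ± 0.579 RPKM with shRNA1 and 22.1 ± 3.50 RPKM with shRNA2, a difference of -1.67. Limma adjusted p for these differences lay between 0.000905 and 0.00428. Interferon stimulated genes were higher with shRNA2 by a median of 0.51 (camera adjusted p = 3.67e-08), with 15 of 37 called, and MYC targets lower by -0.37 (camera adjusted p = 3.67e-08), with 8 of 37 called. With an estimated correlation the smallest adjusted p over lists was 0.678. Of 10660 genes, 510 were higher and 650 lower with shRNA2. Without shRNA1 A 217 genes were called, without shRNA1 B 162, without shRNA2 A 439 and without shRNA2 B 458.

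**Figure D4:**
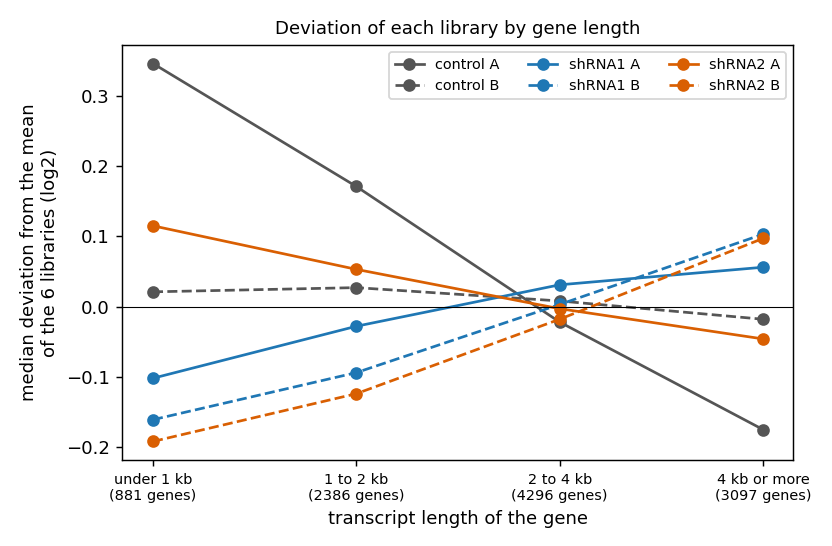
Median deviation of each library from the mean of all 6 (vertical axis, log2) in 4 bins of gene length (horizontal axis, lengths implied by the reads); each line is a library. In the 881 genes under 1 kb control A lies at 0.35 and shRNA2 B at -0.19, and in the 3097 genes of 4 kb or more control A lies at -0.18.

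Libraries also differed by gene length, within groups as well as between them. In the 881 genes under 1 kb, the median deviation from the mean of all libraries was 0.35 in control A and 0.02 in control B, -0.10 and -0.16 in shRNA1 A and B, and 0.12 and -0.19 in shRNA2 A and B. Genes under 1 kb were lower than in the control by a median of -0.32 with shRNA1 and -0.22 with shRNA2. Cytosolic ribosomal protein genes had a median length of 0.728 kb and mitochondrial ribosome genes of 1.40 kb, beside 2.78 kb over all genes tested with shRNA2.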

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

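The tests of a response to the hairpin or vector, of a culture state shared by the controls, of one scaling of all responses and of library scaling for each ribosomal list were chosen only after their results were seen, and the removal of length and GC trends after the data were seen. The genes and lists given first drew attention because the test of the difference between the hairpins passed, for 1160 genes, 15 lists and 39 named genes. The stress response and the cytosolic and mitochondrial ribosome lists were taken up because they were lower with both hairpins, and their difference between hairpins did not pass (camera adjusted p = 0.214, 0.937 and 0.277). Of these 39 genes, all kept their sign without each library in turn and 17 also kept their call.

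Named genes higher with shRNA2 than with shRNA1 that kept their call were SPP1 by a log2 difference of 4.24, S100A12 by 3.72, PINLYP by 3.21, DEFA4 by 2.49, IFI27 by 2.39, H2AFX by 2.25, MMP8 by 2.23, FPR1 by 2.03, SERPINB2 by 1.16 and TNF by 1.14. Those lower with shRNA2 that kept it were HLA-DRA by -3.02, TMEM255A by -2.44, PTGDS by -2.43, CD79B by -1.77, IDH1 by -1.67, MPO by -1.63 and MRPL10 by -1.11. The call was lost without at least 1 knockdown library for EMP1 at 1.89, IFITM1 at 1.45, LTB at 1.16 (0.73 without shRNA1 B), GP9 at 1.07, CD36 at 1.01, HSD17B10 at 0.998, CHMP2A at 0.89, MMRN1 at 0.85, YAP1 at 0.74 and HIST1H2BK at 0.54. It was also lost for HLA-DRB1 at -1.40, MZB1 at -1.16, VEGFA at -1.09, MYC at -1.07, TAZ at -1.001, HLA-DMA at -0.95, TNFAIP3 at -0.90, AMOTL1 at -0.68, TEAD4 at -0.64, PES1 at -0.49, CCNE2 at -0.49 and POLD1 at -0.48.

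Lists higher with shRNA2 had median log2 differences of 0.86 for mature neutrophil genes, 0.54 for NF-kappaB and inflammatory targets, 0.51 for interferon stimulated genes, 0.47 for monocyte and macrophage differentiation, 0.41 for immediate early genes, 0.35 for MHC class I presentation and 0.35 for replication-dependent histones. Smaller differences were 0.20 for lysosome and autophagy, 0.16 for oxidative phosphorylation and 0.16 for the Toll-like receptor pathway. Lists lower with shRNA2 were MHC class II presentation at -0.93, cholesterol synthesis at -0.49, MYC targets at -0.37, fatty acid synthesis at -0.27 and heat shock genes at -0.26. Camera adjusted p of these lists lay between 3.67e-08 and 0.0444 at the preset correlation. Genes that passed the filter against the control with only 1 hairpin may widen such differences. Examples are MMP8 and FPR1 in the mature neutrophil list and HLA-DRA and HLA-DRB1 in MHC class II. With an estimated correlation no list passed (smallest camera adjusted p = 0.678), but with 2 libraries per group that run was too weak to decide. At the preset correlation the call was lost for oxidative phosphorylation without shRNA2 A (-0.02), for heat shock genes without shRNA1 A and without shRNA2 B (-0.13), and for fatty acid synthesis without shRNA1 B (-0.17), without shRNA2 A (-0.14) and with the gene length trend removed (adjusted p = 0.0711). Without shRNA1 B the monocyte difference was 0.28. Without shRNA2 A it was 0.31, and the lysosome difference was 0.12. Without shRNA2 B the differences were 0.35 for oxidative phosphorylation, -0.44 for fatty acid synthesis and 0.54 for histones. With the length trend removed they were 0.09 for oxidative phosphorylation and 0.20 for histones.

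Interferon stimulated genes stood higher with shRNA2 than with shRNA1, the hairpin with the milder fall of TAZ, and the ratio of the median fold with shRNA2 to that with shRNA1, on the log2 scale, was 2.73 over 34 genes (95% bootstrap interval 1.45 to 8.13; 2.23 to 3.23 with each library left out). Over immediate early genes it was 0.13 (-0.13 to 0.56; 0.01 to 0.51 with each library left out) and over NF-kappaB targets 0.27 (-0.38 to 0.70; -0.17 to 0.48), and 4 of 10 other lists called with shRNA1 lay below the interferon list (MHC class II, with 3 genes tested with both, was left out), while the ratio was 2.45 (1.69 to 5.02; 1.84 to 2.97) over MYC targets and loosely measured over monocyte genes (2.87, -7.31 to 5.09; 1.63 to 4.82) and lysosome genes (2.70, 1.04 to 24.8; 1.81 to 4.10). So a common scaling of all responses with the depth of the TAZ fall is argued against by the whole lists, but only weakly. The intervals resample genes of a list, which are not independent replicates. The lists were also chosen for their call with shRNA1, which may lower their ratios. Oxidative phosphorylation and cytosolic ribosomal proteins, among the 4 lower lists, had shRNA1 medians of 0.10 and -0.04 with the length trend removed. Over the 8 interferon stimulated genes called with both hairpins the ratio was 1.37 (1.02 to 2.18). It was 1.09 (1.04 to 1.13) over 791 other genes called the same way with both, there taken from medians of absolute log2 fold changes. Both sets were chosen for a call with each hairpin, which may draw their ratios towards equal change. They are therefore not directly comparable with the ratios of whole lists. A scaling of some lists stays open. A gene length trend is argued against too, since the difference was 0.52 after its removal. A response to the hairpin or vector, which may trigger interferon signalling, and the lower TAZ level cannot be told apart from the difference of 0.51, because each hairpin has its own TAZ level. A vector response equal in all groups would not give this difference, since every group carried a lentiviral hairpin under the same puromycin selection.

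Integrated stress response targets were lower with both hairpins. Control B stood above control A by a median of 0.87 over this list, and without control B the smaller fall went from 0.72 to 0.30, less than 50% of its value (95% bootstrap interval 0.02 to 0.56). So a single aberrant control library may account for part of the fall, and how much is open. With all libraries, camera with an estimated correlation gave an adjusted p = 0.852 and 0.909, in a run too weak to decide. Scaling of the libraries is argued against, with a smallest fall of 0.68 under quantile normalization. In 21 of 38 genes both control libraries lay above all 4 knockdown libraries, and a culture state shared by the controls cannot be told apart from the knockdown because both hairpins use the same controls.

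Transcripts of the cytosolic and mitochondrial ribosome were lower with both hairpins, and the smallest of the 4 median falls was 0.25. A GC content trend is argued against (smallest fall 0.26 after its removal). One aberrant control library is argued against as the whole cause (smallest fall 0.17), but it may account for part of the cytosolic falls. Without control A these went from 0.35 to 0.17 with shRNA1 and from 0.37 to 0.18 with shRNA2, where the call was lost. Control A also deviated most in genes under 1 kb (0.35), so this explanation and a gene length trend are not separate. A gene length trend between libraries stays open. After its removal the smallest fall, of cytosolic ribosomal proteins with shRNA1, was 0.039 (95% bootstrap interval -0.01 to 0.11). The 827 genes under 1 kb outside this list had a median log2 fold change of -0.317 with shRNA1 and -0.194 with shRNA2. The list itself had -0.35 and -0.37, so its fall with shRNA1 was close to that of short genes in general. The other 3 falls lay between 0.11 and 0.23 after the removal and kept their call at the preset correlation. With an estimated correlation, before the removal, camera adjusted p was 0.852 with shRNA1 and 0.909 with shRNA2 for both lists. Scaling is argued against for the mitochondrial list, whose falls were 0.21 and 0.27 under quantile normalization, and stays open for part of the cytosolic falls, which shrank to 0.095 and 0.14, so a response of the ribosomal genes remains a hypothesis.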

How the results depend on the processing

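The voom fit, the removal of length and GC trends and the split of the controls were chosen after the data were seen. TAZ kept its fall under every alternative run for it (-1.29 to -1.51 with shRNA1, -2.18 to -2.70 with shRNA2). Counts under pseudocounts of 0.1 and 1, other filters, quantile normalization, median centring, no variance trend, robust empirical Bayes and removal of the length or GC trend stayed within 1.5 times. Genes called with shRNA1, with shRNA2 and the same way with both numbered 4662, 5044 and 2676 by the authors' statistics, and 379, 494 and 156 with at least a 2-fold change. With shRNA2 the fit of all libraries called 2584 genes. Voom on recovered reads, which also fitted all libraries at once, called 2706 with shRNA2 and 1229 the same way with both. Where an alternative did not enter fewer libraries or genes, the cause was not tested. With each library left out in turn, which leaves a lone library assumed to vary like the other group, counts ranged from 500 to 4447, from 864 to 1934 and from 278 to 1383, the count of differences between hairpins from 162 to 1628, and the correlation of the hairpins from 0.598 to 0.713. With 1 control library per hairpin that correlation was 0.419 or 0.523, and 823 or 968 genes were called the same way. Dropping the quieter shRNA1 libraries left the more variable controls to set the spread. The letters A and B were not stated to pair libraries, and with only 2 letters, which mirror each other, the correlations do not settle a pairing: deviations of same-lettered libraries correlated at 0.26, 0.42 and 0.37 over 10660 genes, and the block raised the counts to 3780, 4170, 2178 and 2396. It ended no list's call. Of 12 lists called with each hairpin, 0 passed with an estimated correlation and 0 with fry. Over all tested lists, called or not, those at an unadjusted p under 0.05 numbered 0 and 1 with an estimated correlation. With fry they numbered 6 and 6, and not all of these were among the called lists. Oxidative phosphorylation with shRNA1 reversed, to 0.10, with the length trend removed. With all libraries kept, named genes lost calls in 20 results with no variance trend and 16 with no filter. They lost 15 with the GC trend removed, 14 with the length trend removed, and at most 7 under the other such settings. Among named genes, calls were lost in 55 results without shRNA1 B, 38 without shRNA1 A, 33 without shRNA2 B, 15 without shRNA2 A, 16 without control A and 12 without control B. Calls were gained in 80 results under the block, 50 without control B, 30 without control A, 33 with voom, 32 with the length trend removed and 21 in one fit of all libraries, and in at most 14 under any other setting. No called gene changed sign, while 7 results that had not passed did (such as EBP with shRNA1, from -0.49 to 0.08 without control A), and the called median of glycolysis and hypoxia with shRNA2 went from -0.39 to 0.003 without control A. Genes near 1 RPKM rest on few reads, so changes there were less firmly measured than in abundant genes.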

Other observations

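Lipid and mitochondrial genes around TAZ moved in both directions. Of 16 genes of cardiolipin synthesis and remodelling, 2 rose and 4 fell with shRNA1 (2 rose and 8 fell adjusted over the list alone; median log2 fold change -0.24, camera adjusted p = 0.171), and 1 rose and 2 fell with shRNA2, also adjusted over the list alone (median -0.12, camera adjusted p = 0.408). HSD17B10, a mitochondrial dehydrogenase, fell from 68.8 ± 8.65 to 21.4 ± 1.27 RPKM with shRNA1, and DNAJC19, a prohibitin partner, from 50.9 ± 1.94 to 28.9 ± 0.845 RPKM. Genes of phosphatidylethanolamine and phosphatidylserine metabolism had medians of 0.10 with shRNA1 (5 of 28 rose and 1 fell; 6 and 1 adjusted over the list alone; camera adjusted p = 0.363) and 0.01 with shRNA2 (3 of 30 rose and 4 fell; 5 and 6 adjusted over the list alone; camera adjusted p = 0.766). ANO6, a phospholipid scramblase, rose from 6.001 ± 1.11 to 12.2 ± 0.592 RPKM with shRNA1. In the list of mitochondrial dynamics, import and cristae, 3 of 29 rose and 3 fell with shRNA1, and 1 rose and 5 fell with shRNA2 (3 and 3, and 2 and 5, adjusted over the list alone). Its medians were -0.11 and -0.10 (camera adjusted p = 0.491 and 0.339). CHCHD3, a scaffold of cristae junctions, rose from 33.9 ± 1.15 to 74.6 ± 0.858 and 81.3 ± 5.21 RPKM with shRNA1 and shRNA2 (limma adjusted p = 0.00238 and 0.00345). Of 26 genes of the tricarboxylic acid cycle 4 rose with shRNA1, and 3 rose and 1 fell with shRNA2 (2, and 3 and 1, adjusted over the list alone), with medians of 0.08 and 0.10 (camera adjusted p = 0.242 and 0.339).

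Lists of cell cycle and stem cell genes did not pass. Of 40 genes of G1/S 1 rose and 3 fell with shRNA1, and 2 rose and 3 fell with shRNA2 (1 and 2, and 2 and 2, adjusted over the list alone), with medians of -0.02 and -0.17 (camera adjusted p = 0.441 and 0.0666). Of 45 genes of G2/M 5 rose and 2 fell with shRNA1, and 4 rose with shRNA2 (3 and 1, and 3, adjusted over the list alone), with medians of 0.03 and 0.09 (camera adjusted p = 0.479 and 0.119). CCNE2, a cyclin of S phase entry, rose from 8.58 ± 0.683 to 22.0 ± 1.79 RPKM with shRNA1 and 15.6 ± 1.24 RPKM with shRNA2. ANLN, a cytokinesis protein, rose with shRNA2 from 19.4 ± 0.0231 to 39.4 ± 0.554 RPKM. Leukaemic and haematopoietic stem cell genes had medians of 0.06 and 0.33 (camera adjusted p = 0.441 and 0.0666), with 4 of 27 rising and 3 falling with shRNA1 (6 and 3 adjusted over the list alone) and 7 of 26 rising and 5 falling with shRNA2 (9 and 6 adjusted over the list alone). MMRN1, which encodes a multimerin of platelets, rose from 12.1 ± 0.128 to 34.6 ± 0.301 RPKM with shRNA2. Genes of neutrophil primary granules went both ways with each hairpin: with shRNA1 6 of 17 rose and 3 fell (7 and 4 adjusted over the list alone), and with shRNA2 4 of 17 rose and 3 fell (7 and 4 adjusted over the list alone), with camera adjusted p of 0.363 and 0.503. CTSG, the granule protease cathepsin G, rose from 242 ± 18.5 to 551 ± 84.6 RPKM with shRNA2, while MPO fell. Toll-like receptor pathway genes had a median of 0.18 and a mean of -0.01 with shRNA1, so median and mean differed in sign, and camera did not call them (adjusted p = 0.243).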
